A study of Mus musculus with 6 samples.

How the data were processed

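RNA came from the node and primitive streak region of mouse embryos between embryonic days 7.75 and 8 (0 to 2 somites), dissected from wild-type embryos and from embryos without Wnt3a function, on a mixed C57BL/6 and 129/Sv background. Per the labels' protocols, 30 to 50 ng of total RNA of each single embryo went through a first amplification cycle, amplified RNA of 3 embryos of one genotype and stage was pooled (600 ng in all) for the second cycle, and each labelled pool was hybridised to 1 Affymetrix mouse whole-genome GeneChip. There were 3 arrays per genotype, so 9 embryos per genotype.

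The deposited table holds 1 intensity per probe set and array on a linear scale, for 45101 probe sets. The submitters' processing notes name RMA, without a version, but the deposited intensities do not have the form of RMA output: they are linear, their distributions differ between arrays, and the mean after trimming 2% at each end is 500 on each of the 6 arrays. That is the form of Affymetrix signals scaled to a common target, and the step that made the table is not given in the sources used here. The tests had been planned for log2 RMA values, with linear values to be turned to log2 first, which was done. No further background was subtracted from the deposited values and no floor was set. Probe sets with a signal of a few units vary widely on the log2 scale. The probe sets' mean log2 value had a median of 6.16, equal to a signal of 71.5.

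The 64 control probe sets were left out. Of the other 45037, 34945 are annotated with 1 gene symbol, 932 with several and 9160 are not listed in the annotation table. By gene ID, 34741 of those with 1 symbol matched the RefSeq genes of assembly GRCm38.p6, and 0 symbols needed an update. A gene was represented by its probe set with the highest mean log2 value over all arrays, which gave 18193 genes. The probe set of the gene T (Brachyury), a fixed member of several lists, is not listed, so T is not reported.

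Null was compared with wild type in R 4.3.3 with limma 3.58.1 (lmFit and eBayes without trend or robust options, no filter on low values), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 23 lists with at least 5 measured members. A further list of sex-linked genes only described the pools. Test, lists, named genes and most alternatives were fixed before the data were examined. Named genes were Wnt3a, 12 genes per direction (the largest changes past the threshold, filled up by the smallest p as values only) and up to 4 members of each list with the smallest p. Other genes named were chosen after their values were seen: Shmt1, Cdx4, Cdx2, Nkd1, Lef1, Tnfrsf19, Dkk1, Evx1, Fst, Mesp2, Tcf15, Msgn1, Mef2c, Hoxb3, Spag9, Sulf2, Hspa4, Sfrp1, Pax3, Foxc1, Lfng and the heart and forebrain markers.

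The labels give both genotypes replicates 1, 2 and 3. Deviations from the genotype means were correlated between arrays of one number, before any fit, over the 18088 probe sets with a mean log2 above 7. The correlations were 0.422, 0.454 and 0.282, against at most -0.0564 between different numbers, and the numbers were taken to pair the arrays (bound 0.1). Deviations within a genotype sum to 0, so positive values within a number push those between numbers below 0 on average. The negative values are therefore no separate evidence of pairing. The restriction to log2 above 7 had not been planned. Over all genes, dim ones included, the correlations were 0.0727, 0.0537 and 0.0284, below that bound, and each array still correlated best with its own number. The labels do not say what a number shares.

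A fit with the replicate number as a block and with eBayes trend and robust options was chosen after several fits had been seen, because it made calls where the planned fit made none. Its results are named as such. The alternatives tried were the mean of a gene's probe sets, every probe set by itself, a filter at the median signal, trend and robust options, array weights, median centring, cyclic loess, the block, leaving out each array, other thresholds, camera with an estimated correlation, and fry. Added after seeing the data were log2(signal + 50), several combinations with the block, trend and robust options over single probe sets, leaving out pairs, and lists without members shared with the Wnt target list.

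The fits were tested on simulated data: 10 simulations of 18193 genes with 200 changed. The changed genes were drawn only from genes at or above the median signal over genes. The simulated values kept the pair differences of the real arrays, with noise taken from the fit with the block. Pairing was thus built in, and the comparison is no independent reason to prefer the paired fit. The planned fit recovered 0% of genes changed by 1 on the log2 scale and 34.3% of those changed by 2, with 3.65% of its calls false. The paired fit with trend and robust recovered 35.1% and 73.1%, with 1.46% false. In both, camera found the changed list in 10 of 10 simulations and an unchanged list in 0. The simulated noise was independent between genes. The simulations therefore cannot show how often camera calls an unchanged list whose members vary together. In the real pools the visceral and yolk sac endoderm list had an estimated correlation of 0.856 between members.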

Results

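Transcripts of the node and primitive streak region, the posterior midline tissue in which Wnt3a is made, were measured in 3 pools of wild-type and 3 pools of Wnt3a null embryos, each pool from 3 embryos. The stage was chosen before the mutant embryos look abnormal, and the question was which genes depend on Wnt3a, a secreted Wnt signalling ligand. Median signals per array ran from 73.7 to 86.4. Correlations between arrays over all genes were 0.930 to 0.939 within a genotype and 0.925 to 0.937 between genotypes. The ratio of 3' to 5' Gapdh signal, a measure of RNA integrity, was 2.09 to 2.39 in the null pools and 2.51 to 3.00 in the wild-type pools, while the same ratio for beta-actin overlapped, at 2.38 to 3.83 and 2.68 to 3.69. Wild-type pool 1 differed in sex composition: its Y-linked Eif2s3y signal was 4.31, against 1053 to 1788 on the other 5 arrays, and its Xist signal was 7440. Null pool 1 had a Xist signal of 5047 with Y-linked signal present, against 1871 to 2707 on the other 4 arrays.

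Wnt3a itself was represented by 1 probe set. Its signal was 910 ± 131 (SD, n = 3) in null and 973 ± 98.8 (SD, n = 3) in wild-type pools, a log2 difference of -0.10 (limma, adjusted p = 1.00). Which part of the gene the null allele alters is not given in the sources used here, and RNA outside an altered part can still be made, so this probe set does not check the labels.

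Among brightly measured genes, several readouts of Wnt signalling had lower signals in null pools. Axin2, a feedback inhibitor of the pathway, had a signal of 1268 ± 37.9 in null and 2627 ± 169 in wild-type pools (SD, n = 3 each), 2.07-fold lower. Cdx1, a caudal homeobox gene of the posterior body axis, was 2.40-fold lower, and the zinc finger gene Sp5 was 3.22-fold lower. No single gene passed the planned test: limma called 0 genes lower and 0 higher of 18193, with 390 lower and 550 higher at an unadjusted p under 0.05 (910 in all by chance) and a smallest adjusted p of 0.0905. The block alone also called 0, with 1147 genes at an unadjusted p under 0.05. The groups did not overlap for 1840 genes, 10.1%, and chance gives 10% for arrays without pairing. Since the arrays were taken as paired, this comparison cannot show whether there was an excess. By pairs, all 3 differences had 1 sign in 30.2% of genes (2681 lower, 2811 higher), and chance gives 25% for independent pairs.

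In the paired fit with trend and robust options, chosen after the data were seen, 9 genes were lower and 2 were higher in null pools. The 9 were Cdx1 (limma, adjusted p = 0.00326), Axin2 (0.00656), Cdx4 (0.00656), Cdkn1a (0.0113), Cited1 (0.0142), Spag9 (0.0248), Sulf2 (0.0396), Dll1 (0.0479) and Sp5 (0.0497). Cdx4, a relative of Cdx1, was 3.45-fold lower. Cdkn1a, a cell cycle inhibitor, was 2.38-fold lower, and Cited1, a transcriptional coregulator, 2.31-fold lower. Dll1, a Notch ligand of presomitic mesoderm, was 1.61-fold lower, at 2857 ± 484 against 4587 ± 739. Irx3, a homeobox gene of the neural plate, was 2.70-fold higher (2098 ± 60.9 against 794 ± 196, adjusted p = 0.00544), and Tbx20, a T-box gene of heart progenitors, was 2.09-fold higher (1337 ± 278 against 644 ± 147, adjusted p = 0.0248). All 11 differed in 1 direction in each of the 3 pairs, as did 30.2% of all genes. A paired fit picks genes whose differences are alike across pairs, so this is no separate support. Other probe sets of Axin2, Sulf2, Spag9 and Tbx20 did not all share the change: the second Axin2 probe set had a log2 difference of 0.26 at signals of 40.5 to 94.2, and the brighter of 2 further Sulf2 probe sets had 0.00. A Spag9 probe set at signals of 77.3 to 144 had -0.04, and 1 of 2 further Tbx20 probe sets, at signals of 3.11 to 15.5, had -0.12. Without pair 3 this fit called 0 genes (smallest adjusted p = 0.0593, limma), although log2 differences in pairs 1 and 2 (Cdx1 -1.27 and -1.21, Axin2 -1.01 and -1.20) were close to those in pair 3 (-1.31 and -0.94) for these 2 genes. Without pair 1 it called 34, and without pair 2 it called 63.

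**Figure D1:**
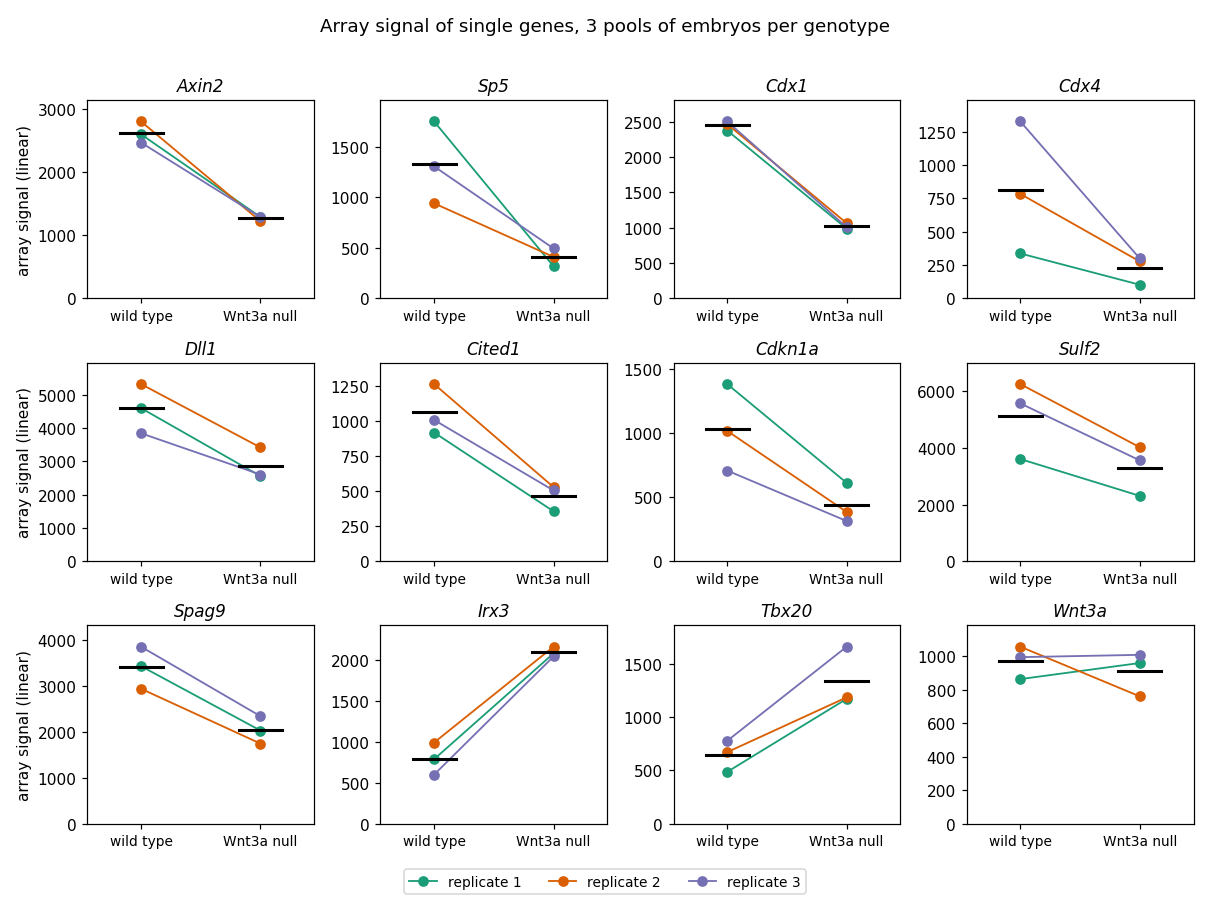
Linear array signal (vertical axes, starting at 0) of the 11 genes past the threshold in the paired fit and of Wnt3a, in wild-type and null pools. Dots are arrays, coloured lines join arrays with the same replicate number, and black bars are means; Cdx1 stands at 1021 in null against 2450 in wild-type pools, while Wnt3a overlaps at 910 and 973.

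As a group, feedback genes and targets of Wnt signalling were lower in null pools. Of 20 measured members 17 had a lower mean log2 signal, the median log2 change was -0.79, and camera gave an adjusted p of 8.21e-10 (0.0447 with an estimated correlation). Over all genes 0 members passed the planned test; adjusted over the list alone 5 were lower, namely Cdx1, Axin2, Notum, Sp5 and Tnfrsf19. Notum, a secreted Wnt deacylase, had 175 ± 48.7 against 513 ± 81.5, and Tnfrsf19, a receptor gene, 1789 ± 138 against 2942 ± 213. Members that did not pass by themselves included Dkk1, a secreted antagonist, with a log2 change of -1.15, Nkd1 with -0.98 and Lef1, a nuclear mediator of the pathway, with -0.65. In the planned design the estimated correlation between members was -0.00817, below the preset 0.01. Correlation between members therefore does not account for the rise to 0.0447. The list kept its call without any single array and lost it with the block and an estimated correlation together (adjusted p = 0.403).

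Genes of the primitive streak and posterior progenitors were lower as a group: 14 of 21 measured members, median log2 change -0.31, camera adjusted p = 0.00148. With an estimated correlation the adjusted p was 0.158. Adjusted over the list alone 2 members were lower, Cdx1 and Sp5, and 0 passed over all genes. Fgf4, a growth factor gene of the streak, had 779 ± 97.3 against 1257 ± 270, Evx1 had a log2 change of -0.97, Cdx2 of -0.52 and Fst of -0.65. The list shares 4 members with the Wnt target list, and without them its adjusted p was 0.162.

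Hox genes, which pattern the body axis, were lower as a group: 20 of 26 measured members, median log2 change -0.37, camera adjusted p = 0.00419 (adjusted p = 0.378 with an estimated correlation). No member passed by itself, over all genes or adjusted over the list alone. Hoxb4 had 268 ± 117 in null and 663 ± 112 in wild-type pools, Hoxb3 had a log2 change of -1.13 and Hoxa4 of -1.60, and Hoxa10 had 1.89, higher in value in each of the 3 pairs, with 889, 151 and 151 in null and 69.6 to 76.9 in wild-type pools. The call was lost without null replicate 1 (adjusted p = 0.180) and without wild-type replicate 3 (0.147).

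Notch pathway genes were lower as a group, with 14 of 21 measured members lower, a median log2 change of -0.20 and a camera adjusted p of 0.0275 (adjusted p = 0.227 with an estimated correlation). Adjusted over the list alone 0 members passed. Hes5, a Notch target, had 123 ± 59.7 against 391 ± 94.6, Hes7, an oscillating repressor of the segmentation clock, 662 ± 10.9 against 1135 ± 288, and Heyl was higher in value at a log2 change of 0.71. The call was lost without null replicate 1 (adjusted p = 0.0854), null replicate 3 (0.114), wild-type replicate 1 (0.0673) or wild-type replicate 3 (0.107).

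Genes of presomitic and paraxial mesoderm, which forms the somites, went both ways. Adjusted over the list alone 2 of 20 measured members were lower, Cited1 and Tbx6, a T-box gene that specifies this tissue (656 ± 46.0 against 1098 ± 26.7). Msgn1, a regulator of presomitic fate, had a log2 change of -1.13. Some members had higher values without passing: Ripply2 326 ± 70.0 against 105 ± 74.2, Mesp2 a log2 change of 1.25 and Tcf15 of 0.78. Others, also named after their values were seen, stood near 0 or below, with Pax3 at -0.10, Foxc1 at 0.14 and Lfng at -1.11. The list was not called (camera adjusted p = 0.641, median and mean log2 change 0.04, test direction lower), whereas fry's test for changes in either direction gave an adjusted p of 0.00154. That test also passed for 5 other lists: Wnt targets (adjusted p = 2.53e-05), streak (7.31e-04), Notch (9.97e-04), Wnt ligands and receptors (0.00800) and neural plate (0.00849).

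Genes of lateral plate, cardiac and extraembryonic mesoderm were higher in null pools as a group: 16 of 21 measured members, median log2 change 0.44, camera adjusted p = 0.00367 (adjusted p = 0.227 with an estimated correlation). Adjusted over the list alone 0 passed. Next to Tbx20, the highest-ranked members were Isl1, a heart progenitor gene, with 816 ± 194 against 483 ± 83.2, Gata6 with 743 ± 78.5 against 512 ± 85.1, and Myl7, an atrial myosin light chain gene, with 275 ± 154 against 108 ± 50.4. Mef2c had a log2 change of 0.98. The call was lost without null replicate 3 (adjusted p = 0.0665) and without wild-type replicate 1 (0.0575).

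Lists of blood and endothelium and of definitive endoderm were higher by a narrow margin, each with a camera adjusted p of 0.0478 (adjusted p = 0.254 and 0.324 with an estimated correlation). In the blood and endothelium list 17 of 21 measured members were higher, with Kdr, a receptor of endothelial progenitors, at 619 ± 45.9 against 449 ± 86.9, while Lmo2 had a log2 change of -0.88. In the endoderm list 14 of 18 were higher, including Otx2 (684 ± 605 against 92.4 ± 34.4) and Krt19 (749 ± 134 against 493 ± 91.5). In neither list did a member pass adjusted over the list alone. The blood and endothelium call was lost without null replicate 1 (adjusted p = 0.0578), 2 (0.0616) or 3 (0.114) and without wild-type replicate 1 (0.0765) or 3 (0.107). The endoderm call was lost without null replicate 1 (0.289) or 3 (0.0977) and without wild-type replicate 1 (0.0673), 2 (0.0794) or 3 (0.107).

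Neural plate genes and FGF feedback genes were not called by the planned test and were called with the replicate block, with the trend option and after a filter at the median signal. Of 26 measured neural genes 16 were higher, with a median log2 change of 0.36 and a camera adjusted p of 0.0752, or 0.0327 with the block. Irx3 passed adjusted over the list alone, and Zic5, a zinc finger gene of the neural plate, had 1348 ± 50.1 against 812 ± 109. Neurog2 went the other way at a lower signal, with 30.2 ± 8.03 against 76.3 ± 36.8 and a log2 change of -1.25. Of 19 FGF and MAPK feedback genes 12 were lower, with a median of -0.12 and a camera adjusted p of 0.0752, or 0.0444 with the block. With estimated correlations the adjusted p was 0.254 for both lists, and 0.403 for both with the block as well. Of the FGF list, Fgf4 was lowest in p and its values are given above with the streak genes. Fgf5 went the other way, with 149 ± 92.9 in null and 35.1 ± 23.3 in wild-type pools, a log2 change of 2.28.

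**Figure D2:**
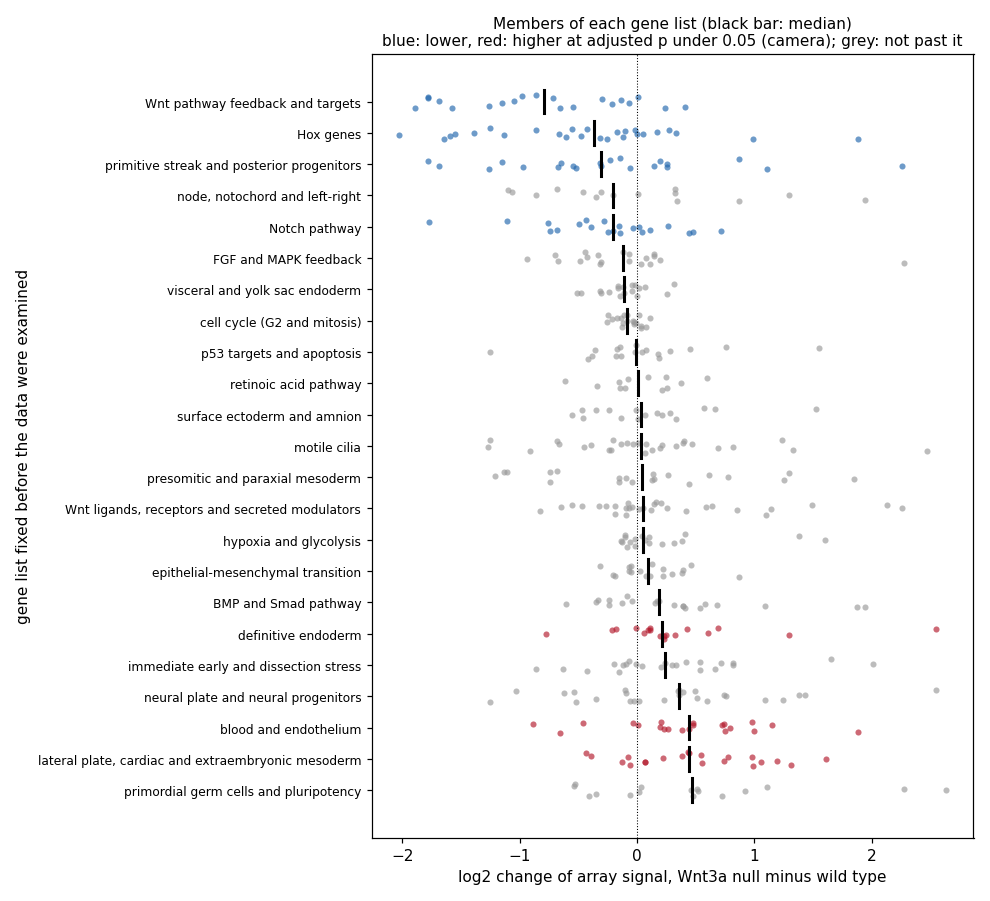
Log2 change of array signal, null minus wild type (horizontal axis), for each measured member of the 23 tested gene lists (vertical axis). Dots are genes, black bars are medians, and colour marks lists past the camera threshold; the Wnt target list has the lowest median, -0.79.

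The remaining lists were not called by camera. Adjusted p was 0.297 for Wnt ligands, receptors and secreted modulators, where Sfrp5, a secreted Wnt inhibitor, passed adjusted over the list alone (249 ± 30.8 against 89.8 ± 24.5), Sfrp1 had a log2 change of 0.85 and Wnt5b of -0.83. It was 0.992 for node, notochord and left-right genes, whose median (-0.21) and mean (0.00) log2 change differed in sign. Nodal, a left-right signalling ligand, had 216 ± 70.0 against 479 ± 233. The value was 0.829 for motile cilia, 0.485 for epithelial-mesenchymal transition, 0.118 for the BMP pathway, 0.992 for retinoic acid, 0.702 for surface ectoderm and amnion and 0.0767 for germ cells and pluripotency. Visceral and yolk sac endoderm had 0.365, p53 targets and apoptosis 0.641 (median -0.01, mean 0.03), mitotic cell cycle genes 0.254, hypoxia and glycolysis 0.377, and immediate early and stress genes 0.138. Among the last, Fos had 483 ± 124 against 156 ± 50.4 and an adjusted p of 0.539.

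The 12 genes with the smallest p in each direction were mostly near the floor of the arrays. Of those lower in null 11 of 12 lay below the median probe set signal, with Cdx1 the exception, and of those higher 12 of 12 did. Cd209e had the smallest p of all, at 26.0 ± 1.73 against 3.08 ± 0.444 (limma, adjusted p = 0.0905). Lypd2 had 6.04 ± 0.435 against 60.7 ± 20.7, and Egr3, an immediate early gene, 110 ± 21.3 against 15.3 ± 3.11, with the second Egr3 probe set going the other way at a log2 change of -1.31.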

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

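The test of the whole Shmt1 transcript level and the splits of the single-gene counts were chosen only after the results were seen. For heart tissue and for a younger stage, the number given from each test (the median, and the camera value) was settled after a first run, with the written predictions left unchanged. The fit used for probe sets below, with the replicate block, trend and robust options, was also chosen after seeing the data.

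One signal lay outside the comparison of named genes. A probe set to which the annotation gives no single gene symbol, unnamed here, was higher in null pools. Its signal was 3052, 1574 and 2051 in the null pools and 571, 264 and 889 in the wild-type pools, a log2 change of 2.07 (limma, paired fit over 45037 probe sets, adjusted p = 0.0373), above the wild-type level in 3 of 3 pairs. In the same fit 2 other unnamed probe sets were lower, with log2 changes of -2.21 and -1.14.

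Shmt1, a gene of folate metabolism on chromosome 11, lies 32 measured genes from Wnt3a, and 2 of its probe sets were lower in null pools: 1 by a log2 change of -2.06 (adjusted p = 1.88e-04, the smallest of all probe sets) and 1 of -1.20 (adjusted p = 0.00516). The tables argue against a change of the whole transcript, because the 2 other probe sets stood at 0.25 and -0.07, with the latter's interval from -0.29 to 0.16. A candidate explanation is strain variants that travelled with the targeted Wnt3a allele in this mixed background, altering probe binding or transcript ends. Among probe sets of the 100 measured genes on each side, 41 of 352 (11.6%) had an unadjusted p under 0.05, against 8.08% of the other 34588 (one-sided Fisher's exact p = 0.0124), with 19 lower and 22 higher. Probe sets of one gene are not independent, and a regulated change of 1 Shmt1 isoform by Wnt3a stays open as untested; Hspa4, 83 measured genes away, was the only neighbour called (log2 change 0.87, adjusted p = 0.0228).

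Lists higher in null pools were lateral and cardiac mesoderm, blood and endothelium, definitive endoderm and, with the block, the neural plate; explanations were weighed for the lateral, cardiac and neural genes only. Heart tissue carried along in the null dissections cannot be told apart from an effect of the genotype. The 4 contractile genes outside the fixed lists and above the median signal had a median log2 change of 0.13 with an SD of 0.17. Together these lie below the lateral mesoderm median of 0.44, within the bound set beforehand against this explanation. That bound does not settle it, since the wild-type signal of 3 of them (Tpm1 2494, Tnnc1 261, Actc1 256) could hide a small share. How large a share they would hide was not tested, and Isl1 and Gata6 were higher from wild-type signals of 483 and 512. The remaining contractile gene, Tnni1 (log2 change 0.24), is a single gene whose pairs ran from -0.90 to 1.41. Heart markers not in that set went both ways, with Myl7 at 1.31, Tnnt2 at 1.19, Myh7 at 0.82 and Myh6 at 0.54, against Actn2 at -0.62, Nkx2-5 at -0.43 and Myl4 at -0.41. Anterior neural tissue cannot be told apart from an effect of the genotype, since 0 of 9 forebrain and midbrain markers outside the fixed lists reached the median signal; 5 more sit in a fixed list, and the highest signals in null pools were 115 for Hesx1 and 99.2 for Six3. Otx2, a forebrain and midbrain gene that the fixed neural and endoderm lists hold, had 684 against 92.4 and was higher in 3 of 3 pairs (log2 change 2.55, limma, paired fit over single probe sets, adjusted p = 0.0373). The same fit over genes did not call Otx2. A younger stage of the null pools is open too, with no clear shift of the contractile genes (camera in limma, unadjusted value 0.662). A change of mesodermal and neural fate without Wnt3a is the biological explanation the design names, and it was not tested separately.

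The 6 arrays can be divided into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The planned single-gene counts are 0, which any of the 10 reaches, so the divisions say nothing about them (highest other values 1 lower and 0 higher). The real division gave 7 lists, 1 of 10 divisions reached that number, and the highest other value was 3. Among the 4 divisions that part all 3 pairs, the paired fit with trend and robust gave 11 genes for the real one and at most 0 for the others, and camera with the block gave 9 lists against at most 3. The paired fit with trend and robust had been chosen because it made calls on the real division, so its contrast was partly fixed in advance. In the other divisions differences by genotype also enter the noise, which lowers their counts. In several of the other divisions the visceral and yolk sac endoderm list had the smallest adjusted p, down to 5.21e-08, a structure of the pools that does not follow genotype.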

How the results depend on the processing

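The fits with the replicate block joined to other options, log2(signal + 50), the left-out pairs and the lists without shared members were chosen only after the result was seen. So was the fit with trend and robust options over single probe sets. All other settings were fixed before the data were examined. Named genes other than Wnt3a kept their direction in 1983 of 1992 values over 127 genes, and Wnt3a turned without null replicate 2. Trend and robust options and the block leave each log2 change as it was, so those values could not turn. Many of these genes were also picked for a small p in the same arrays. The share therefore does not measure how robust their direction is. Of 57 named genes with several probe sets, 41 had all of them on 1 side of 0. The block changed no other call than those given beside the results. Among the planned settings, array weights, centring, cyclic loess, every probe set by itself and a fold threshold left the counts of single genes at 0. The 11 genes of the paired fit with trend and robust lost their calls without pair 3, where 0 of 11 remained with a smallest adjusted p of 0.0593 while all 11 kept their direction in the other pairs, Sulf2 for example with log2 differences of -0.65 and -0.64 against -0.65. The cause of that loss was not tested. The fit had picked these 11 genes for differences alike across pairs, so their kept direction is no separate support. Their calls also rest on the variance model, since the block alone called 0. Leaving out dim probe sets or adding 50 to the signal did not bring calls in the planned design (smallest adjusted p 0.319 and 0.375, against 0.0905).

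With the mean of all probe sets of a gene, 4 genes turned direction: Bcl2l11 0.10, Bmp7 -0.63, Eif2s3y -0.14 and Nusap1 0.12 (log2). Adjusted p of lists was 0.0831 for blood and endothelium, 0.0932 for definitive endoderm, 0.880 for motile cilia and retinoic acid (both turned to lower) and 0.672 for p53 targets (turned to higher). With the filter at the median signal it was 0.00598 for FGF feedback, 0.00196 for the neural plate, 0.0938 for blood and endothelium and 0.882 for retinoic acid (turned to lower).

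Trend and robust options called 1 gene lower (Cdx1). Over single probe sets, a setting chosen after the result was seen, they called 1 probe set of Shmt1 lower but not that of Cdx1. Camera took the trend option only and gave 0.0337 for FGF feedback, 0.0199 for the neural plate, 0.0215 for germ cells and pluripotency and 0.956 for retinoic acid (turned to lower). Array weights gave 0.0520 for definitive endoderm and 0.865 for visceral endoderm (turned to higher). Centring gave 0.0416 for the neural plate and for germ cells, and 0.910 for the node (turned to higher). Cyclic loess gave 0.0587 for blood and endothelium. At an adjusted p under 0.1, 1 gene was higher. The block gave 0.0444 for FGF feedback, 0.0327 for the neural plate, 0.991 for motile cilia and 0.998 for retinoic acid (both turned to lower).

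Camera with an estimated correlation called 1 list: 0.227 for Notch and for lateral mesoderm, 0.158 for the streak, 0.378 for Hox, 0.254 for blood and endothelium and 0.324 for definitive endoderm. The estimate was below the preset 0.01 for Notch (-0.0295), the streak (-0.0108) and blood and endothelium (-0.0134). For these lists correlation between members does not account for the higher adjusted p. Fry for changes in 1 direction called 1 list (6 for changes in either direction): 0.175 for Notch, 0.0763 for the streak, 0.398 for Hox, 0.187 for lateral mesoderm, 0.168 for blood and endothelium, 0.244 for definitive endoderm and 0.999 for retinoic acid (turned to lower). The block with an estimated correlation called 0 lists: 0.403 for Wnt targets, Notch, the streak, lateral mesoderm and blood and endothelium, 0.628 for Hox, 0.634 for definitive endoderm and 0.998 for motile cilia and retinoic acid (both turned to lower).

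The paired fit with trend and robust called 9 genes lower and 2 higher. The list test with the block took the trend option only and called 11 lists, with 0.0169 for FGF feedback, 0.00934 for the neural plate, 0.0181 for germ cells, 0.0392 for the cell cycle and 0.809 for retinoic acid (turned to lower). Among genes at or above the median signal the paired fit called 11 lower and 4 higher, with 10 of the 11 kept, over single probe sets 14 and 8, without pair 1 19 and 15, and without pair 2 35 and 28. With log2(signal + 50), FGF feedback, the neural plate and germ cells had 0.0320 and retinoic acid 0.925 (turned to lower). The block after the filter gave 0.00629 for FGF feedback and the neural plate and 0.883 for retinoic acid (turned to lower). Without members shared with the Wnt target list 4 lists were called, with 0.162 for the streak and 0.0558 for blood and endothelium and for definitive endoderm, whose members did not change but whose adjustment over the lists did. Apart from fewer members or arrays in a setting, the cause of these differences was not tested.

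Without both replicate 1 arrays 3 lists were called: 0.140 for Notch, 0.121 for Hox, 0.139 for blood and endothelium, 0.245 for definitive endoderm, and, with turned direction, 0.930 for presomitic mesoderm and p53 targets and 0.857 for surface ectoderm, while Xist stood at a log2 difference of 0.017. With 1 array left out, 3 to 8 lists were called. The lowest and highest adjusted p were 0.388 and 0.931 for presomitic mesoderm, 0.0167 and 0.114 for Notch, 0.0385 and 0.385 for FGF feedback, 0.425 and 0.934 for the node, 0.0647 and 0.897 for motile cilia, and 9.27e-04 and 0.180 for Hox. They were 0.455 and 0.920 for retinoic acid, 0.00263 and 0.0665 for lateral mesoderm, 0.0408 and 0.114 for blood and endothelium, 0.00753 and 0.289 for definitive endoderm, and 0.00714 and 0.981 for visceral endoderm. Direction turned for presomitic mesoderm without null 1 or wild-type 3, for the node without null 2 or wild-type 3, and for motile cilia without null 1, null 3, wild-type 2 or wild-type 3. It also turned for retinoic acid without null 3 (0.589), wild-type 1 (0.912) or wild-type 2 (0.528), and for visceral endoderm without wild-type 2. Log2 differences ran from -0.18 to 0.023 for Wnt3a, -0.56 to 0.41 for Xist, -0.031 to 4.17 for Eif2s3y and -0.19 to 2.05 for Kdm5d. These 3 sex-linked genes turned without wild-type replicate 1, and Xist also without null replicate 2 (0.15).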

Other observations

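No test was added here after the results were seen. Visceral and yolk sac endoderm genes varied together between pools, with an estimated correlation of 0.856 between members, against -0.00817 in the Wnt target list. The list was lower without wild-type replicate 1 (camera adjusted p = 0.00714) and higher, again past the threshold, without wild-type replicate 2. Adm, a hypoxia-responsive peptide hormone gene, had 6193 ± 1362 in null and 2533 ± 1615 in wild-type pools (limma, adjusted p = 0.975). Its other probe set had 1813, 753 and 1024 in null and 346, 133 and 520 in wild-type pools, a log2 change of 1.95. Signal of the 18S rRNA control was 5822 and 5951 on the arrays of replicate 1, against 10135 to 13541 on the other 4.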
